A study of Homo sapiens with 3 samples.

How the data were processed

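Gene expression was measured by droplet single-cell RNA sequencing in 3 cultures of human mesenchymal stromal cells. Per the labels' protocols, cells were grown in medium with 20% fetal calf serum and ascorbate, detached with trypsin, passed through a 40 µm strainer, sorted for live cells and loaded at about 5000 cells per library with the Chromium single cell 3' kit version 2, and libraries were read on a NextSeq 500 with 26 bases of read 1 and 98 of read 2. The labels give the same culture text, which describes tooth pulp digestion, for all 3 sources, so how bone marrow and adipose cells were isolated is not given in the sources used here. Per the submitters' processing notes, Cell Ranger 2.1.1 and the GRCh38 genome build were used.

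The deposited matrices hold UMI counts per gene and barcode, whole numbers with no normalization, for 33694 genes, in 2 copies per library that differed in 0 entries. A UMI tags 1 captured RNA molecule, so copies made by PCR are counted once, and the 3' kit counts a transcript near its end, so genes that overlap or have near-identical copies can be confused. The matrices hold barcodes already chosen as cells, so empty droplets and the free RNA in them could not be measured.

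Barcodes with at least 1000 UMIs, at least 500 genes and under 20% mitochondrial UMIs were kept, which removed 3 BMSC, 11 ADSC and 2 SHED barcodes. The median kept cell had 3177, 3788 and 3362 genes and 3.44%, 2.98% and 2.48% mitochondrial UMIs. Scrublet, run through scanpy 1.11.5, called 3, 2 and 2 doublets, 0.06%, 0.06% and 0.04% of the kept cells. Why it called so few was not tested, and doublets remain in the main values. Cell cycle phases were called from S and G2/M gene scores, which gave 75.9%, 86.9% and 83.0% of cells in G1.

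The kept cells of a library were summed per gene and divided by the library's total to give scaled counts (CPM). A gene counted as at least 4-fold apart when it had at least 10 CPM in the higher library and the ratio was 4 or more, with 0 UMIs set at a floor of 3 UMIs, which is 0.039 CPM in BMSC, 0.0425 CPM in ADSC and 0.0374 CPM in SHED. A ratio against that floor is printed as at least N-fold. That value is the ratio at the floor, and the lower end of its 95% interval is smaller. For HAND2 in SHED over BMSC the lower end was 992-fold, against 1221-fold at the floor. The 95% interval of a ratio is the exact conditional (Clopper-Pearson) interval and that of a CPM the exact Poisson interval. With 1 library per group no test was run and no p-value exists, and the intervals leave out the spread between donors, cultures and library preparations. Sex-linked genes were left out of the counts.

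Before the data were examined, 45 gene lists, the cell type markers, the thresholds and the rule for named genes were fixed. The 4 HOX lists also hold 3 non-coding RNAs of these clusters, so values for the 39 HOX genes alone are given beside those of the lists, a step chosen after the data were seen. For each pair the rule took the 10 largest ratios in each direction at 50 CPM or more, without mitochondrial genes, ribosomal protein genes, clone identifiers and a fixed set of excluded genes, then up to 4 members of each list with the largest ratios at 10 CPM or more, and 7 fixed genes (MKI67, TOP2A, THY1, NT5E, ENG, PTPRC and CD34). CDKN1A, FST and SOX10, and the genes drawn in the plots of pooled levels, were chosen after their values were seen. Some genes that the rule takes are not reported here. A list is described by the measured members at least 2-fold apart and, with 3 or more, by its median log2 ratio and the percentile of that median among 10000 random lists of the same size matched on level, which describes these libraries only. The pooled comparison was run on simulated counts for 33694 genes in each pair. Of 100 genes set 6-fold apart it called 100, and of 100 set 2.5-fold apart it called 0. The intervals held the true ratio in 95.0% to 97.5% of these changed genes. The changed genes were drawn from levels above the 10 CPM threshold, and the counts held Poisson counting error alone. This checks the code and does not measure the spread between donors or cultures.

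For shares of cells, each cell was thinned at random to 3000 UMIs. Clusters were made for each library alone with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.5 (leidenalg 0.10.2), and a cluster was named only with at least 3 fixed markers 2-fold higher and at least 1 among its 10 leading genes. Positions are from GENCODE 29 on GRCh38, in which 33132 of the 33694 gene identifiers were found; the annotation release behind the deposited matrices is not given in the sources used here. Alternatives covered scaling (TMM factors from edgeR 4.0.16 and median-of-ratios factors), the genes in the total, the weight of each cell, barcode filters, doublets, phase, thresholds, thinning depth and clustering resolution. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and R 4.3.3.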

Results

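The series holds 3 droplet single-cell RNA libraries of cultured human mesenchymal stromal cells, the adherent fibroblast-like cells that can form bone, fat and cartilage in culture. The libraries came from bone marrow (BMSC), adipose tissue (ADSC) and the pulp of shed deciduous teeth (SHED), with 1 library per source, and the series title gives gene profiles across tissues as the subject. The labels give about 5000 live cells loaded per library after sorting. The files held 5253 barcodes for BMSC, 3438 for ADSC and 4847 for SHED, of which 5250, 3427 and 4845 passed the filters. The deposited totals were 76855009 UMIs (counted RNA molecules) for BMSC, 70735925 for ADSC and 80316815 for SHED, and the median kept cell had 13784, 19051 and 16009 UMIs. Because each source had 1 library, there were no replicates and no significance test was possible. Every interval below is a 95% interval that covers counting error only, and a difference between libraries is a difference between these 3 cultures, in which source, donor and culture cannot be separated.

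All 3 libraries had the messenger RNAs of the surface proteins used to define mesenchymal stromal cells, and low levels of PTPRC and CD34. THY1, which encodes CD90, stood at 365 CPM (UMIs scaled to the library total) in BMSC, 791 CPM in ADSC and 374 CPM in SHED. NT5E, which encodes CD73, stood at 79.4 CPM, 74.5 CPM and 97.9 CPM in the same order. ENG, which encodes the TGF-beta co-receptor CD105, was 3.90-fold lower in SHED than in BMSC (interval 3.75 to 4.07) and 5.19-fold lower than in ADSC (4.99 to 5.40). PTPRC, the pan-leukocyte gene, had 2 UMIs in BMSC, 2 in ADSC and 3 in SHED, and CD34 had 14, 14 and 26. CD14, a monocyte receptor gene, stood at 14.7 CPM in SHED against 0.47 CPM in BMSC and 0.74 CPM in ADSC, and CD68, also on the myeloid list, at 36.4 CPM in SHED, 37.5 CPM in BMSC and 23.1 CPM in ADSC. CD14 is a negative surface marker of mesenchymal stromal cells, and the only 1 of 10 on that list at 10 CPM or more in any library. Without thinning, 12.3% of SHED cells had a CD14 UMI. None of the lymphoid, red cell, endothelial, Schwann cell or skeletal muscle lists had a member at 10 CPM or more in any pair. Among the 16 measured surface genes of the positive list, SHED had 2 at least 2-fold higher and 6 at least 2-fold lower than BMSC, with ALCAM 3.53-fold lower (3.40 to 3.68) and the tetraspanin gene CD9 4.30-fold higher (4.13 to 4.47).

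**Figure D1:**
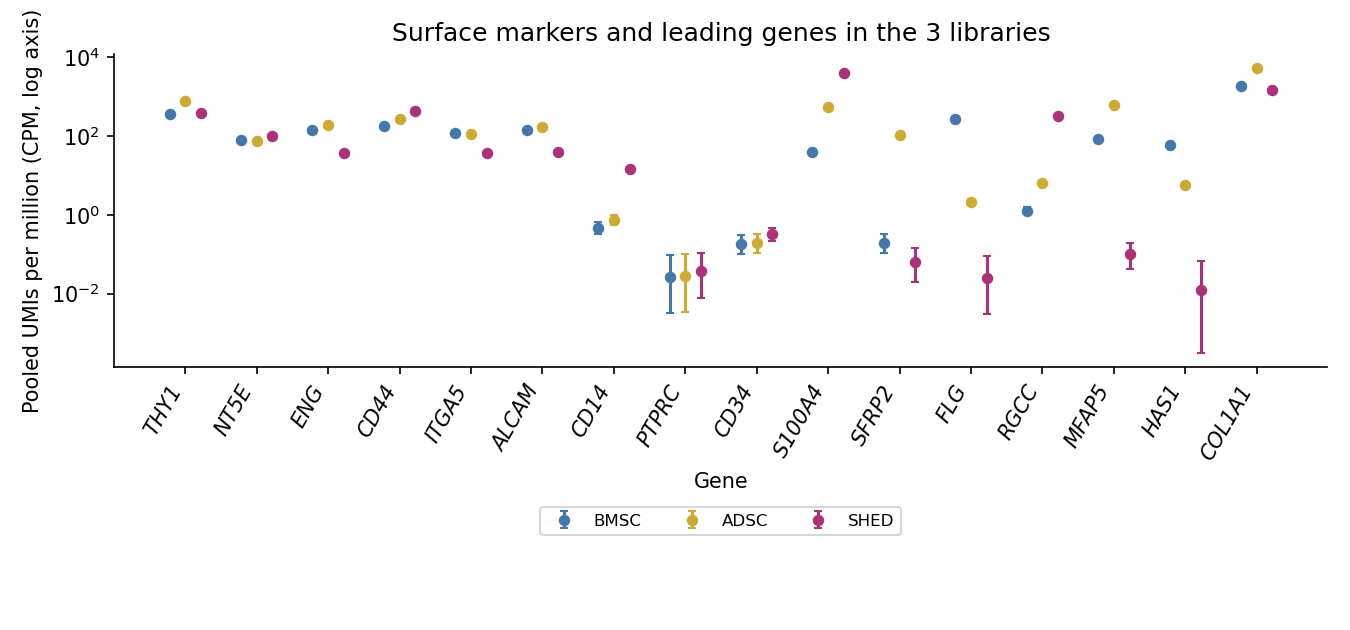
Pooled level of 16 genes in each library, in CPM on a log axis, with 1 point per library and 95% Poisson intervals that cover counting error only. THY1 lies between 365 CPM and 791 CPM and NT5E between 74.5 CPM and 97.9 CPM, PTPRC and CD34 lie below 1 CPM in each, and S100A4, SFRP2, FLG, RGCC, MFAP5 and HAS1 lie far apart.

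After every cell was thinned to 3000 UMIs, 5.33% of BMSC cells (exact binomial interval 4.74 to 5.98), 8.43% of ADSC cells (7.52 to 9.41) and 1.98% of SHED cells (1.61 to 2.41) had UMIs of THY1, NT5E and ENG together. No cell was below 3000 UMIs, so none was left out. Without thinning the shares were 50.7%, 64.2% and 31.2%, and the order of the 3 libraries was the same as after thinning. A cell without a UMI may still express the gene. These shares therefore depend on depth and are not the shares of cells that express all 3 genes. Of the 3 genes, ENG had the lowest thinned share in SHED, at 11.5% of cells (10.6 to 12.4) against 36.4% in BMSC and 41.0% in ADSC. These libraries held no cell type known to lack the 3 genes, so the share that free RNA alone would give was not measured.

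MKI67 and TOP2A, both made in dividing cells, were highest in BMSC. A UMI of either gene was found in 12.7% of thinned BMSC cells (11.9 to 13.7), 5.17% of ADSC cells (4.45 to 5.96) and 6.01% of SHED cells (5.35 to 6.71). The ADSC and SHED intervals overlapped, and without thinning their order was the other way round, at 14.3% and 13.3%, beside 25.4% in BMSC. MKI67 stood at 32.0 CPM in BMSC, 13.3 CPM in ADSC and 16.9 CPM in SHED, and TOP2A at 46.7 CPM, 13.7 CPM and 25.1 CPM. In cells called G1 the order of MKI67 between SHED and ADSC was the other way round. MKI67 is itself on the G2/M list behind the phase calls, so that order can come from the selection. Of 35 measured mitosis genes, 12 were at least 2-fold lower in ADSC than in BMSC and none was higher, among them CENPF (2.42-fold lower, 2.27 to 2.58) and ANLN (2.57-fold lower, 2.33 to 2.84). In SHED against BMSC, 3 of 35 mitosis genes were at least 2-fold lower and 1, RANGAP1, was 2.55-fold higher (2.38 to 2.73).

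**Figure D2:**
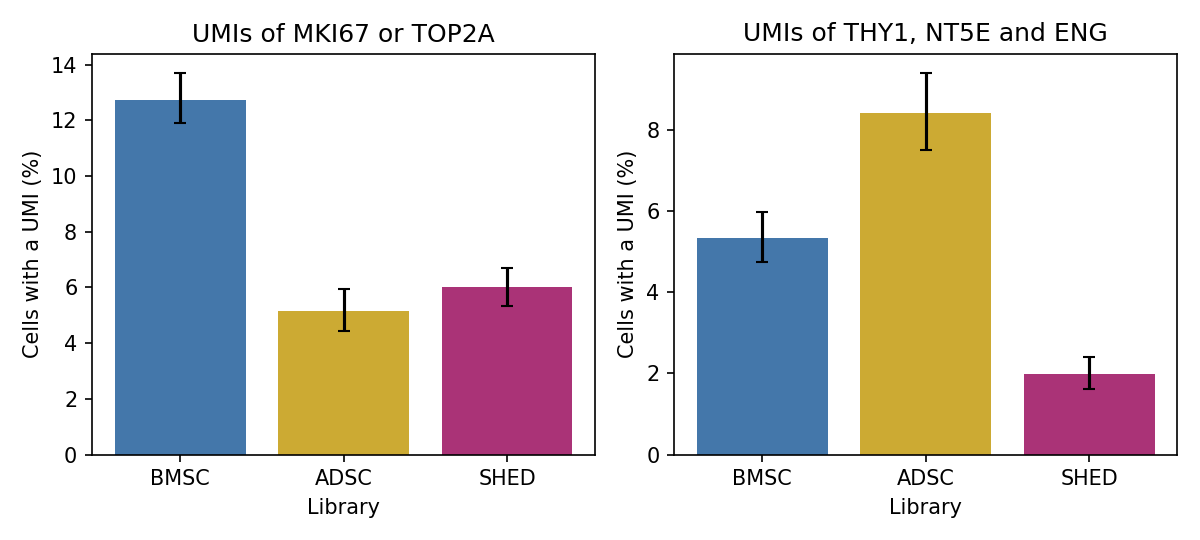
Percent of cells with a UMI of MKI67 or TOP2A (left) and with UMIs of THY1, NT5E and ENG together (right), after thinning each cell to 3000 UMIs, with 1 bar per library and exact 95% binomial intervals that cover counting error only. BMSC is highest at 12.7% on the left, and SHED is lowest at 1.98% on the right.

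The first comparison set ADSC against BMSC. SFRP2, which encodes a secreted modulator of Wnt signalling, was 542-fold higher in ADSC (329 to 970), at 106 CPM against 0.2 CPM. The matrix protease gene MMP3 was 101-fold higher in ADSC (80.5 to 129), SCRG1 81.0-fold (66.2 to 100.3), the lectin gene CLEC2B 43.6-fold (37.0 to 51.8) and the interferon-inducible gene IFI27 37.7-fold (33.2 to 42.9). A UMI of MMP3 was found in 12.2% of thinned ADSC cells (11.1 to 13.3) and in 35.9% without thinning. In ADSC clusters of 141 and 113 cells MMP3 stood at 726 CPM and 756 CPM, against 59.2 CPM and 88.1 CPM outside each. Also higher in ADSC were the oxytocin receptor gene OXTR (34.2-fold), COMP, a cartilage matrix gene (24.2-fold), MFAP4 (20.7-fold), the hyaluronan-binding protein gene TNFAIP6 (19.6-fold) and S100A4, a calcium-binding protein gene (13.9-fold). On the BMSC side, the urea transporter gene SLC14A1 was 247-fold higher (160 to 405), FLG, which encodes filaggrin, 130-fold (110 to 153), KIAA1644 82.1-fold (61.4 to 112), the keratin-associated gene KRTAP1-5 53.6-fold (43.2 to 67.3) and CHI3L1 39.6-fold (34.1 to 46.2). A UMI of FLG was found in 18.6% of thinned BMSC cells (17.5 to 19.7) and in 33.1% without thinning. SUGCT (17.9-fold), DPP7 (15.8-fold), the gap junction gene GJA1 (14.5-fold), the hyaluronan synthase gene HAS1 (10.8-fold) and SORT1 (10.8-fold) completed the 10 largest ratios in BMSC among genes at 50 CPM or more.

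Of 8 measured bone formation genes, 5 were at least 2-fold lower in ADSC than in BMSC and 1 was higher, with a list median of -1.69 on the log2 scale (percentile 0.0 among 10000 random lists matched on level). DLX5 was 34.5-fold lower in ADSC (24.6 to 49.7), BMP4 25.8-fold (17.9 to 38.5), and RUNX2, the master regulator of bone formation, 5.60-fold (5.12 to 6.13). Among 14 genes of cell cycle arrest and senescence, 7 were at least 2-fold higher in ADSC and 0 lower, among them MMP3, MMP1 (34.5-fold) and IGFBP5 (8.86-fold, 8.50 to 9.24). Several of these are secreted proteins with functions outside senescence, and the cyclin-dependent kinase inhibitor gene CDKN1A stood at 371 CPM in ADSC and 324 CPM in BMSC. Fibrillar collagens and their partners had 7 of 19 members at least 2-fold higher in ADSC and 2 lower, including LOX, a collagen cross-linking enzyme gene (2.94-fold, 2.88 to 3.00), and ASPN (85.4-fold, 47.5 to 172). Pericyte-associated genes had 4 of 7 members at least 2-fold lower in ADSC and 1 higher, with lower members such as MCAM (4.32-fold, 3.93 to 4.75) and ANGPT1 (3.01-fold, 2.75 to 3.30). Of 6 measured neural crest genes 3 were at least 2-fold higher in ADSC and 0 lower, with a median of 1.14 on the log2 scale (percentile 99.9), among them TWIST2 (7.39-fold, 6.94 to 7.88) and SNAI2 (3.19-fold, 3.07 to 3.32). The list has 23 members. TFAP2A (0.91 CPM in ADSC, 1.54 CPM in BMSC) and TFAP2C (0.54 CPM and 0 CPM) were below the 10 CPM needed to be measured. The stromal chemokine gene CXCL12 was 5.54-fold lower in ADSC (5.23 to 5.87), and VCAM1 72.3-fold lower (39.1 to 151).

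In all, 113 genes were at least 4-fold higher in ADSC and 110 at least 4-fold higher in BMSC, of 7369 genes at 10 CPM or more in either library, which is 3.0%. The log2 CPM of these genes had a Pearson correlation of 0.911 across genes, which are not independent replicates.

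The second comparison set SHED against BMSC. RGCC, a cell cycle regulator gene, was 248-fold higher in SHED (204 to 306). S100A4 stood at 4004 CPM in SHED and 38.4 CPM in BMSC, a ratio of 104 (101 to 108), and lies on chromosome 1 at 153543613 to 153550136 on the minus strand (GRCh38, GENCODE 29). The smooth muscle actin gene ACTG2 was 58.1-fold higher in SHED, the microfibril gene FBN2 44.5-fold (38.2 to 52.1), and MSX1, a transcription factor gene of tooth and jaw development, 21.8-fold (19.9 to 23.9). At 50 CPM or more, the other 5 genes with the largest ratios were IFI27 (20.6-fold), FAM213A (17.3-fold), FAM129A (14.4-fold), CARD16 (12.2-fold) and SPON2 (9.65-fold). In the other direction FLG had 21131 UMIs in BMSC and 2 in SHED, a ratio of 11040 with a counting interval of 3056 to 91190. These BMSC UMIs came from 33.1% of the BMSC cells, counted without thinning. HAS1 (4678 UMIs against 1), the small heat shock gene HSPB7 (7212 against 2) and MFAP5 (6636 against 8) followed, and CHI3L1 was 377-fold lower in SHED (246 to 609) and FNDC1 352-fold lower (254 to 503). ELN, which encodes elastin, was 71.0-fold lower in SHED (58.7 to 86.8), CYP1B1 70.7-fold (64.8 to 77.4), CRIP2 65.1-fold (57.7 to 73.8) and IFITM10 48.5-fold (41.2 to 57.6).

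HOX genes, which record position along the body axis, were nearly absent from SHED. HOXA10 had 3164 UMIs in BMSC and 1 in SHED, and HOXC9 had 1793 and 1. HOXC8, on chromosome 12 at 54009106 to 54012362, had 1772 UMIs in BMSC and 0 in SHED, which is at least 617-fold higher in BMSC, and HOXB7 was at least 1130-fold higher. All 4 measured members of the HOXA list (3 HOXA genes and the non-coding RNA HOTAIRM1), 3 of 3 HOXB members, 4 of 4 HOXC members and the 1 HOXD member were at least 2-fold lower in SHED. With genes at 0 UMIs set at 3 UMIs, the list medians were at most -9.52, -8.35 and -9.30 on the log2 scale for the A, B and C clusters. Over the 42 members of the HOX lists, which are 39 HOX genes and 3 non-coding RNAs of the clusters, the sum was 369 CPM in BMSC, 483 CPM in ADSC and 0.274 CPM in SHED, and 67.1% of thinned BMSC cells (65.8 to 68.4), 74.3% of ADSC cells (72.8 to 75.7) and 0.103% of SHED cells (0.0335 to 0.241) had a UMI of any of them. Unthinned, the shares were 98.1%, 98.9% and 0.413%. For the 39 HOX genes alone the sums were 345 CPM, 437 CPM and 0.187 CPM and the thinned shares 64.7%, 70.4% and 0.0619%.

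Transcription factors of the jaw and tooth mesenchyme went the other way. Of 14 measured members, 9 were at least 2-fold higher in SHED than in BMSC and 2 lower, with a median of 3.83 on the log2 scale (percentile 100.0). HAND2 had 3827 UMIs in SHED and 0 in BMSC, at least 1221-fold higher, FOXF1 was at least 743-fold higher and LHX8 at least 657-fold. Neural crest genes had 4 of 7 measured members at least 2-fold higher in SHED and 0 lower, with TFAP2C at least 497-fold higher, NES 65.3-fold (44.4 to 100.2), TFAP2A 19.6-fold (16.3 to 23.8) and TWIST2 7.24-fold (6.80 to 7.72). SOX10, a gene of migrating crest and glia, had no UMI in any library.

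**Figure D3:**
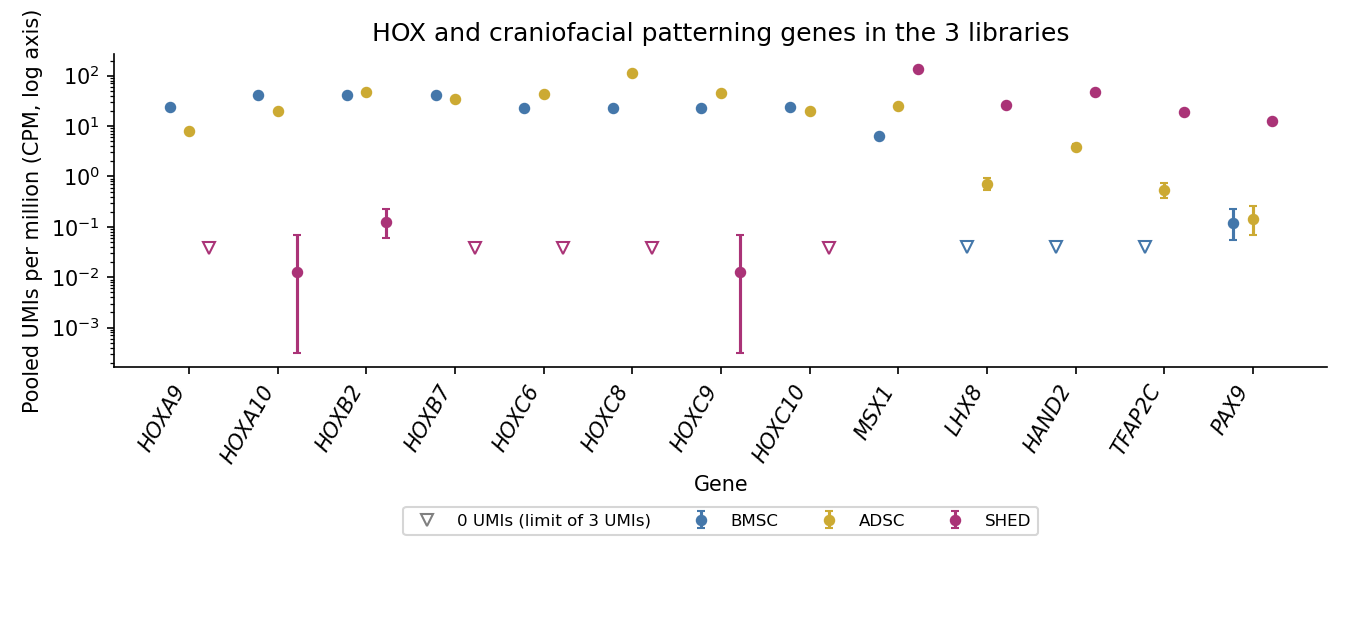
Pooled level of 8 HOX genes and 5 other transcription factor genes in each library, in CPM on a log axis, with 1 point per library, 95% Poisson intervals that cover counting error only, and open triangles at the level of 3 UMIs where a library had 0 UMIs. The HOX genes lie between 7.87 CPM and 111 CPM in BMSC and ADSC and below 1 CPM in SHED, while MSX1, LHX8, HAND2, TFAP2C and PAX9 are highest in SHED.

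TGF-beta and BMP pathway genes had 9 of 17 measured members at least 2-fold lower in SHED than in BMSC and 2 higher. ID3, an immediate target of BMP signalling, was 14.4-fold lower (14.0 to 14.8), ID2 8.96-fold (8.54 to 9.41), SMAD7 7.79-fold (6.89 to 8.83) and the activin subunit gene INHBA 6.51-fold (6.22 to 6.81). FST, which encodes the activin antagonist follistatin, stood at 689 CPM in SHED against 192 CPM in BMSC. Matricellular genes had 9 of 14 members at least 2-fold lower in SHED, such as POSTN (29.8-fold, 28.4 to 31.3) and VCAN (9.81-fold, 9.38 to 10.3), and 2 higher, among them SPON2. Fibrillar collagen genes had 7 of 18 lower and 1 higher, with COL11A1 11.9-fold lower (11.2 to 12.6) and COL12A1 5.87-fold lower (5.70 to 6.04). Of 4 measured cartilage genes 3 were at least 2-fold lower in SHED, among them the aggrecan gene ACAN (15.2-fold, 11.7 to 20.1). Basement membrane and microfibril genes had 6 of 19 members at least 2-fold higher in SHED and 6 lower, and COL4A1, a basement membrane collagen gene, was 34.9-fold lower in SHED (32.0 to 38.0) while COL15A1 was 28.1-fold higher (20.1 to 40.6). Cholesterol synthesis genes had 8 of 18 members at least 2-fold higher in SHED and 0 lower, including MVD (4.07-fold, 3.83 to 4.32) and FDPS (3.03-fold, 2.96 to 3.12). Heat shock and unfolded protein response genes had 6 of 21 higher and 0 lower, with TRIB3 4.48-fold higher (4.31 to 4.66), HSP90B1 2.76-fold (2.72 to 2.81) and ATF4 2.64-fold (2.60 to 2.68). Of 21 measured genes of secreted vessel and tissue growth factors, 5 were at least 2-fold higher in SHED and 4 lower, and the list median of 0.03 on the log2 scale changed sign under other settings. MDK (6.32-fold, 6.07 to 6.59), PTN (6.36-fold, 6.02 to 6.71) and IGF2 (5.39-fold, 4.94 to 5.87) were among the higher members.

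Between these libraries 145 genes were at least 4-fold higher in SHED and 227 at least 4-fold higher in BMSC, of 7445 genes, or 5.0%. Scaling by TMM factors moved the median log2 ratio of all measured genes by 0.152 and median-of-ratios factors by 0.184, toward SHED, so list medians of that size carry no direction.

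The third comparison set SHED against ADSC. The integrin gene ITGA8 was 156-fold higher in SHED (115 to 217), FAM213A 152-fold (107 to 224), the growth factor gene PTN 56.4-fold (48.2 to 66.3), RGCC 50.3-fold (45.8 to 55.3), ACTG2 43.2-fold (37.8 to 49.7) and the tendon transcription factor gene MKX 33.3-fold (27.5 to 40.6). CARD16 (23.1-fold), RAMP1 (22.4-fold), FABP3 (16.5-fold) and TMEM158 (16.3-fold) followed at 50 CPM or more. Higher in ADSC were HSPB7 (14035 UMIs against 2), MFAP5 (43575 against 8), COMP (3731 against 2) and SFRP2 (7482 against 5). HOXC8 had 7853 UMIs in ADSC and 0 in SHED, at least 2975-fold higher in ADSC. LRRC32 (930-fold, 519 to 1863), SCUBE3 (833-fold, 357 to 2567), PCOLCE2 (279-fold, 180 to 456) and ISLR (154-fold, 124 to 194) were also among the 10 largest ratios in ADSC at 50 CPM or more.

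The HOX and craniofacial lists divided SHED from ADSC as they divided it from BMSC. All 3 measured members of the HOXA list (HOXA7, HOXA10 and the non-coding RNA HOTAIRM1), 4 HOXB, 4 HOXC and 1 HOXD members were at least 2-fold lower in SHED, and 10 of 13 craniofacial members were at least 2-fold higher and 1 lower, with FOXF1 137-fold (82.7 to 245) and PAX9 87.2-fold (47.2 to 182). As a list, neural crest genes did not divide them this way: of 9 measured, 3 were at least 2-fold higher in SHED and 2 lower. The list median of -0.03 on the log2 scale changed sign under other scaling. The 3 higher in SHED were TFAP2C (36.1-fold, 26.2 to 51.2), TFAP2A (33.25-fold, 25.9 to 43.3) and NES (5.93-fold, 5.21 to 6.78). The 2 lower included ZIC1, at least 476-fold higher in ADSC. TWIST2 stood at 105 CPM in SHED and 107 CPM in ADSC. Fibrillar collagen genes had 14 of 19 members at least 2-fold lower in SHED and 0 higher, with a median of -1.56 on the log2 scale (percentile 0.0), and included BGN (10.8-fold lower, 10.4 to 11.2) and COL5A1 (5.91-fold, 5.70 to 6.13). Of 13 matricellular genes 9 were at least 2-fold lower in SHED and 0 higher, with POSTN 68.3-fold lower (65.2 to 71.7) and TGFBI 13.1-fold lower (12.9 to 13.3). TGF-beta and BMP genes had 11 of 17 at least 2-fold lower and 4 higher, with ID2 7.33-fold lower (6.98 to 7.71) and BMP4 38.6-fold higher (26.9 to 57.5). Bone formation genes had 5 of 8 at least 2-fold higher in SHED and 3 lower, such as MSX2 (22.5-fold higher, 15.8 to 33.1) and ENPP1 (10.5-fold lower, 9.34 to 11.8). In SHED against BMSC the same list had 2 of 9 at least 2-fold higher and 4 lower, with a median of -0.95 on the log2 scale. Of 16 senescence-list genes 6 were at least 2-fold lower in SHED and 1 higher, with IGFBP3 36.4-fold lower (33.7 to 39.4). CXCL12 was 9.13-fold higher in SHED than in ADSC (8.64 to 9.66), and the Wnt ligand gene WNT5A 8.92-fold higher (8.28 to 9.62).

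This pair had 169 genes at least 4-fold higher in SHED and 238 at least 4-fold higher in ADSC, of 7231 genes, or 5.6%. Genes at least 4-fold above both other libraries numbered 50 in BMSC, 62 in ADSC and 81 in SHED, and genes at least 4-fold below both numbered 29, 32 and 119. Of 35 lists with a median in each pair, the median was at least 2-fold higher in ADSC for 2 and in BMSC for 3, higher in SHED for 2 and in BMSC for 6, and higher in SHED for 2 and in ADSC for 8. Under both TMM and median-of-ratios factors, 4 lists were higher in SHED than in BMSC and 5 lower, and the 3 lists higher in BMSC than in ADSC became 2.

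Each library was also clustered alone, which gave 6 clusters in BMSC, 7 in ADSC and 5 in SHED. Clusters with mitosis genes such as MKI67, CDC20, PLK1 and TOP2A among their leading genes, called cycling-like, held 619 and 475 BMSC cells, 512 ADSC cells and 743 SHED cells. No other cluster met the marker rule for a named class. In ADSC, 113 cells formed a cluster with a median of 8162 UMIs, 13.0% mitochondrial UMIs and 4.1% ribosomal protein UMIs, against library medians of 19051, 2.98% and 21.8%, and it was led by SLIT3, COMP, MMP3 and LAMA2. The largest SHED cluster, of 1647 cells, had among its leading genes LINC01444, FST, FJX1 and TRIB3, and the largest BMSC cluster, of 2074 cells, had FLG, PAPPA and COL11A1. Cluster sizes were not compared between sources.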

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

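The alternatives below were chosen before the data were examined, except these, chosen after seeing the data: leaving out the highest 4% of Scrublet scores, keeping cells between 0.5 and 2 times the median UMI count, leaving excluded genes out of clustering, leaving the 3 non-coding RNAs out of the HOX lists for shares of cells, and, for the lists alone, the total without mitochondrial and ribosomal protein genes and the filter at under 10% mitochondrial UMIs. The number of lists at least 2-fold apart, used here to sum up the list medians, was also chosen after the data were seen. No named gene ratio of 4-fold or more and no list median of 2-fold or more changed sign under these alternatives. Counts of genes at least 4-fold apart stayed within 1.5 times under every change of scaling, barcodes, doublets, cell weight and phase, and moved with the thresholds, by construction. In the order higher and lower in ADSC than BMSC, higher and lower in SHED than BMSC, and higher and lower in SHED than ADSC, the counts were 244, 315, 331, 479, 443 and 503 at 2 CPM or more, 44, 35, 37, 77, 44 and 86 at 50 CPM or more, and 331, 388, 420, 739, 446 and 583 at 2-fold or more. Lists at least 2-fold higher in SHED than BMSC numbered 2 in the main values and 4 under both TMM and median-of-ratios factors, and those lower 6 and 5, since these factors shift the median of all genes in that pair by 0.152 and 0.184. Lists lower in ADSC than BMSC numbered 3 and, under either factor, 2. For BMSC, ADSC and SHED, the share of cells with an MKI67 or TOP2A UMI was 8.31%, 2.89% and 4.15% at 1500 UMIs, 18.2%, 8.14% and 8.81% at 6000 UMIs, and 25.4%, 14.3% and 13.3% without thinning, and that with UMIs of THY1, NT5E and ENG was 1.14%, 1.84% and 0.392%, then 18.6%, 22.1% and 6.92%, then 50.7%, 64.2% and 31.2%; at 6000 UMIs 125, 59 and 121 cells were left out. Resolution 1.0 gave 11 clusters in BMSC and 10 in SHED, and resolution 0.25 gave 3 in ADSC, so the number of clusters depends on the resolution. Of 1050 single list medians under alternatives, 341 lay outside their narrow counting interval, and 99.9% shifted by under 0.5 on the log2 scale; of 4620 named gene ratios, 880 did, and 99.1% shifted by under 0.5. Of the smaller values, 7 gene ratios (PTPRC in 3 pairs, CD34 and NT5E in ADSC against BMSC, CD68 in SHED against BMSC, and MKI67 in SHED against ADSC, at -0.41 in G1 cells against 0.35) and 16 list medians of at most 0.11 changed sign, and the cause was not tested. So few doublets were called that leaving them out says little about doublets. Depth limits genes at 0 UMIs to lower bounds. No paired analysis was possible because each source has 1 library.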

Other observations

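The tests of free RNA or swapped barcodes from SHED were chosen after the result was seen. Of 12 measured insulin-like growth factor genes, 4 were at least 2-fold higher in SHED than BMSC and 4 lower. IGFBP2 stood at 40.8 CPM in SHED, 16.6 CPM in BMSC and 0.06 CPM in ADSC, and IGFBP4 was 5.40-fold lower in ADSC than BMSC (5.32 to 5.49). Of 14 measured interferon-response genes, 5 were at least 2-fold higher in SHED than BMSC and 2 lower, with IRF1 3.25-fold higher (2.90 to 3.66). Of 9 measured Wnt genes in SHED against ADSC, 4 were at least 2-fold higher and 4 lower, including WNT5B (6.19-fold higher, 5.89 to 6.51) and DKK1 (12.8-fold lower, 12.2 to 13.5). Nuclear-encoded respiratory chain genes had 28 of 28 within 2-fold between ADSC and BMSC and between SHED and ADSC, and 27 of 28 between SHED and BMSC. The keratin gene KRT7 stood at 113 CPM in ADSC, 62.6 CPM in BMSC and 16.3 CPM in SHED.

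Different shares of cycling cells were a candidate explanation for genes set apart. BMSC, ADSC and SHED had 11.9%, 6.7% and 9.3% of cells called S, and 12.2%, 6.4% and 7.7% called G2/M. These shares differed by less than 4-fold. With equal levels per phase, they could not by themselves set a gene 4-fold apart. The values in G1 cells were therefore largely fixed in advance and are no independent evidence. In cells called G1, 95.5% of the 223 genes at least 4-fold apart between ADSC and BMSC stayed so in the same direction, as did 97.3% of 372 between SHED and BMSC and 98.0% of 407 between SHED and ADSC. Tissue source, donor and culture history remain open, since each source has 1 library.

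HOX genes were near 0 in SHED, and lower capture of genes at this level in that library is a candidate technical explanation. Over 4159 other genes at the level of the 11 members of the HOX lists (10 HOX genes and a non-coding RNA) with 10 CPM or more in both BMSC and ADSC, the median log2 ratio of SHED to the mean of the other libraries was -0.13, against -9.80 or lower for the HOX list members, of which 6 had 0 UMIs in SHED, and 4 of the 4159 were at least 100-fold lower. This argues against lower capture at that level. The tissue of origin is a hypothesis that 1 library per source cannot test.

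HAND2, with 3827 UMIs in SHED and 0 in BMSC, had 271 UMIs in ADSC, and LHX8, with 2061 and 0, had 51, which could come from SHED cells or SHED RNA in that library. Of the 265 ADSC cells with a UMI of either gene, 97.4% had a UMI of a HOX list member (94.6 to 98.9), against 99.1% of the other ADSC cells, whereas SHED cells almost lack these UMIs, which argues against SHED cells as the whole source. The ADSC level of HAND2 was 8.05% of its SHED level, 9.22 times (8.12 to 10.4) the upper limit of 0.873% set by ITGA8, the gene at 50 CPM or more in SHED with the lowest such ratio, which argues against SHED RNA as the whole source of the HAND2 UMIs. For LHX8 the level was 2.81% and the multiple 3.22 (2.39 to 4.25), whose lower end is under the 3 times asked for, so SHED RNA stays open for LHX8. Low expression of HAND2 in the ADSC culture is a hypothesis, and a difference between donors was not tested.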
